A study of Homo sapiens with 10 samples.

How the data were processed

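The series holds 10 RNA-seq libraries of MCF-7, an established oestrogen receptor-positive human breast cancer line. Per the labels, the cells were kept in medium with 10% charcoal-stripped serum and sampled after 72 h. Experiment A has 3 libraries labelled vehicle and 3 labelled as treated with conditioned medium of PreNeu (cm-PreNeu). Experiment B has 2 libraries treated with conditioned medium of LOX-1-positive neutrophils (cm-LOX1) and 2 with cm-PreNeu, and no vehicle library. Per the labels' protocols, polyadenylated RNA was selected and libraries were made with a strand-keeping kit. The labels call the libraries of a group biological replicates without saying how the cultures were separated, so p-values measure the spread between these libraries, part of which may be technical.

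The labels of experiment A conflict. The titles and treatment tags call 3 libraries vehicle and 3 cm-PreNeu, and the descriptions assign the libraries titled vehicle to table columns whose headers carry the letters CM, which the series' design text uses for conditioned medium, and those titled cm-PreNeu to columns whose headers carry CTRL. Groups here follow titles and tags, and each library of experiment A is therefore called "labelled vehicle" or "labelled cm-PreNeu". If the headers are right, every direction given for experiment A reverses.

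The authors deposited 1 table of gene-level counts per experiment, and all values are whole numbers. Per the submitters' processing notes, FastQC 0.11.9, STAR 2.6.1c, RSEM 1.3.3 and DESeq2 1.28.1 were used with GRCh38; the annotation release and the strand setting of the counting are not given in the sources used here. The planned test assumed RSEM estimates that need rounding, and no rounding was needed. The tables hold 64792 and 63140 gene identifiers, of which 58126 are shared, and 58207 and 62541 were matched to a table of gene names. Symbols were found for 91.0% of the genes tested in experiment A and 92.3% in experiment B. Coordinates are those of GENCODE v29 on GRCh38.

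The tables were not counted alike. Among 6692 genes of at least 20 CPM (here a count scaled to the library total alone) in experiment B, 393 (5.87%) were below 0.1 of that level in experiment A. EIF3C had 291 to 518 counts per library in experiment A and 11171 to 14773 in experiment B. Of 180 protein-coding genes of the major histocompatibility complex region, 171 averaged under 10 counts in experiment A and 69 in experiment B. HLA-E, TAP1 and PSMB8 were at 0 counts in every library of experiment A. Each experiment was therefore tested within its own table, and the antigen presentation list in experiment A lacks most of its HLA members.

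Total counts ranged from 48006914 to 53541110 per library in experiment A and from 16854985 to 20143071 in experiment B. A level of 3 counts, the limit that a count of 0 allows, corresponds to between 0.0560 and 0.0625 CPM in experiment A and between 0.149 and 0.178 CPM in experiment B, for counting error only. Count differences between libraries of a group exceeded sampling noise in every pair, with a chi-square per degree of freedom of at least 19.8, so no library was counted as a duplicate.

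Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low genes were removed with filterByExpr, libraries were scaled with TMM, and groups were compared by the quasi-likelihood F test (two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were computed as the size of the log2 fold change over the square root of F. Levels are CPM, on library totals multiplied by the TMM factors (0.920 to 1.09 in experiment A, 0.988 to 1.01 in experiment B), ± SD over the libraries of a group. The level of 3 counts and the cut of 20 CPM above are on totals without these factors. Fixed gene lists, 30 in number, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 tested members. The lists, designs, tests and alternatives were fixed before the data were examined, apart from the alternatives and tests named as later choices. The alternatives were DESeq2 1.42.0, limma-voom, 3 other scalings, 2 other low-count filters, a test against a fold change of 1.2, a replicate block, all 10 libraries in 1 fit, removal of mitochondrial and ribosomal protein genes, each library left out, an estimated correlation, and fry.

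Genes were named by a fixed rule. It takes 9 genes chosen in advance, the 8 genes with the largest change in each direction among called genes with a symbol, a mean of at least 100 counts and groups that do not overlap, and up to 4 called members of smallest p of each list described. Where no gene was called, it takes the 5 of smallest unadjusted p; this can be read with or without the symbol, count and overlap conditions, and both readings are given. Members of lists in experiment B beyond that rule are named as chosen after their values were seen.

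Same-numbered libraries of experiment B carry a shared code in their column headers and were taken as paired in the replicate block and where pairs are set apart. Their deviations from the group means correlated at 0.273 across genes. The first principal component, with 47.7% of the variance, parted the pairs (-34.7 and -18.0 against 29.3 and 23.3). The main fits, main list tests, left-out fits and simulation did not use the pairing. A fit of experiment B with 1 library left out has 1 library in a group and mixes the pair difference with the treatment. The headers of experiment A hold no such code, and its same-numbered libraries were not taken as paired.

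The procedure was tested on simulated counts with 200 changed genes, with the homologous recombination list raised by 0.7 log2 besides and with no pair difference. For experiment A, over 16277 genes, 28% of genes changed 1.5-fold, 68% of those changed 2-fold, 92% of those changed 4-fold and 100% of those changed 8-fold were called. For experiment B, over 14465 genes, the shares were 10.2%, 34%, 86% and 96%. Unchanged genes made up 3.91% and 0.806% of calls.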

Results

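Gene expression was measured by RNA-seq in MCF-7 breast cancer cells exposed for 72 h to neutrophil-conditioned medium. Experiment A set 3 libraries labelled cm-PreNeu against 3 labelled vehicle, at 48006914 to 53541110 counts each, and experiment B set 2 cm-PreNeu libraries against 2 cm-LOX1 libraries, at 16854985 to 20143071 counts each. The series title names homologous DNA repair and sensitivity to PARP inhibition, so repair genes are given first. The titles and the column headers of experiment A disagree on which libraries received conditioned medium; groups follow the titles, and every direction in experiment A reverses if the headers are right.

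The comparison in experiment A asks how MCF-7 cells under cm-PreNeu differ from cells under vehicle. Genes of homologous recombination were higher in the libraries labelled cm-PreNeu: of 41 tested members, 30 were higher, 1 was lower and 10 were not called, with a median log2 fold change of 0.72 (camera adjusted p = 1.16e-05 with the preset correlation, adjusted p = 0.498 with an estimated correlation, and fry adjusted p = 0.00427). BRCA2, which loads the recombinase onto resected DNA, stood at 10.5 ± 4.22 CPM in the libraries labelled vehicle and 36.4 ± 6.21 CPM in those labelled cm-PreNeu (SD, n = 3 each; log2 fold change 1.80 ± 0.28 SE, edgeR adjusted p = 0.000874). Genes of mitosis differed most among the lists that were higher, with all 34 members higher and a median of 1.96 (adjusted p = 0.529 with an estimated correlation). Inflammatory targets of NF-kB lay in the opposite direction, with 13 of 16 tested members lower, 2 higher and a median of -2.45 (adjusted p = 0.220 with an estimated correlation). The oestrogen receptor gene ESR1 stood at 35.4 ± 7.45 CPM in the libraries labelled vehicle and 385 ± 54.5 CPM in those labelled cm-PreNeu (log2 fold change 3.44 ± 0.17, edgeR adjusted p = 2.19e-06).

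Over all genes, edgeR called 8922 of 16569 tested genes (53.8%), 4470 higher and 4452 lower in the libraries labelled cm-PreNeu. Changes over 2-fold made up 2089 of the higher and 1728 of the lower genes. The groups did not overlap for 62.8% of tested genes, where chance gives 10%. With library sizes alone the median of all genes shifted by 0.24 log2 and the calls split into 6870 higher and 3019 lower, and with upper-quartile factors into 5858 and 3453, so changes below about that shift depend on the scaling.

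Among the other fixed repair genes, BRCA1 stood at 22.3 ± 7.29 CPM in the libraries labelled vehicle and 49.6 ± 8.25 CPM in those labelled cm-PreNeu (log2 fold change 1.15 ± 0.24, edgeR adjusted p = 0.00373). PALB2, the partner that joins BRCA1 to BRCA2, had a log2 fold change of 0.11 ± 0.09 and was not called (edgeR adjusted p = 0.336), though it was with library sizes alone (0.35, adjusted p = 0.0112) and with upper-quartile factors (0.26, adjusted p = 0.0377). RAD51, the recombinase, lay at 0.322 ± 0.0880 and 0.708 ± 0.147 CPM (log2 fold change 1.13 ± 0.31, edgeR adjusted p = 0.0142); its counts in experiment A were far below those in experiment B, and its call was lost with DESeq2 (adjusted p = 0.072), with no low-count filter (adjusted p = 0.0548) and without labelled cm-PreNeu replicate 3 (adjusted p = 0.0745). PARP1, the target of PARP inhibitors, stood at 177 ± 16.1 and 286 ± 17.7 CPM (log2 fold change 0.69 ± 0.09, edgeR adjusted p = 0.000342). TP53 had a log2 fold change of 0.24 ± 0.08 (edgeR adjusted p = 0.0308). The call was lost without labelled vehicle replicate 1 or 3 or labelled cm-PreNeu replicate 1 or 3 (adjusted p = 0.114, 0.09, 0.137 and 0.0901), with no low-count filter (adjusted p = 0.0872), with all 10 libraries in 1 fit (adjusted p = 0.0662) and in the test against a fold change of 1.2 (adjusted p = 0.521). Within the homologous recombination list, the called members of smallest p were RMI2 (log2 fold change 1.35), RAD51B (1.08), BARD1 (1.63) and RPA3 (1.01). Adjusted over the list alone, 31 members were called.

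**Figure D1:**
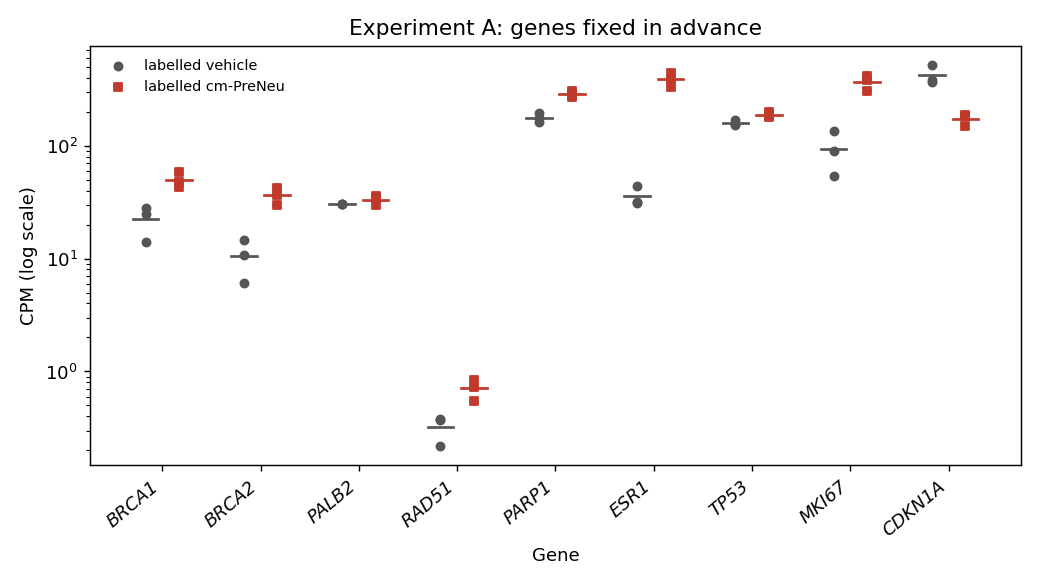
CPM on a log scale (vertical axis) of the 9 genes fixed in advance (horizontal axis) in the 3 libraries labelled vehicle (grey circles) and the 3 labelled cm-PreNeu (red squares) of experiment A, with a bar at each group mean. The groups do not overlap for any gene drawn but PALB2, and ESR1 shows the widest gap, 35.4 against 385 CPM.

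Lists of cell division and other repair routes were also higher in the libraries labelled cm-PreNeu with the preset correlation. With an estimated correlation they were not called (adjusted p = 0.529 for replication, mitosis and mismatch repair, and adjusted p = 0.466 for Fanconi anaemia). The DNA replication list had 35 of 39 members higher and a median of 0.89, with POLE (log2 fold change 1.38) and GINS1 (1.65) among them. In the mitosis list, KIF20A stood at 11.1 ± 4.10 and 82.2 ± 20.2 CPM (log2 fold change 2.89) and FOXM1, a transcription factor of mitotic genes, had a log2 fold change of 2.23. MKI67, a marker of cycling cells, had a log2 fold change of 1.99 ± 0.29, and CDKN1A, which encodes the cell cycle inhibitor p21, one of -1.28 ± 0.15. Labelled vehicle replicate 2 stood apart from the other libraries of its group, at -44.4 on the second principal component against 20.2 and 26.5, and had the lowest levels in it of MKI67 (53.9 against 134 and 89.0 CPM) and BRCA1 (14.0 against 27.9 and 24.8 CPM). Without it the median was 1.73 for mitosis, 0.73 for replication and 0.61 for homologous recombination, and these lists were called. The Fanconi anaemia list had 14 of 20 members higher and a median of 0.71, with FANCD2 at a log2 fold change of 1.62. The mismatch repair list had 6 of 9 higher, a median of 0.38 and a camera adjusted p of 0.0378, which was 0.0832 without labelled vehicle replicate 2 and 0.0609 without labelled cm-PreNeu replicate 3. Lists of end joining (median -0.03), base excision (0.12) and nucleotide excision (0.11) were not called, although POLB, the polymerase of base excision, had a log2 fold change of -1.84 and LIG1 one of 1.35.

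Inflammatory, interferon and stress lists were lower in the libraries labelled cm-PreNeu with the preset correlation. With an estimated correlation none was called, with adjusted p = 0.220 for NF-kB, antigen presentation and STAT3, 0.466 for integrated stress, 0.483 for epithelial, 0.498 for unfolded protein and NRF2, and 0.529 for interferon, cholesterol and mitochondrially encoded genes. ICAM1, an adhesion molecule, stood at 74.6 ± 11.9 CPM in the libraries labelled vehicle and 3.72 ± 0.674 CPM in those labelled cm-PreNeu, and IL6 at 42.9 ± 11.6 and 0.0912 ± 0.00509 CPM. The type I interferon list had 19 of 29 members lower and a median of -1.12, with STAT1 at a log2 fold change of -1.45. The STAT3 and acute phase list had 8 of 13 lower and a median of -1.28, with OSMR at -3.90. The integrated stress list had 15 of 21 lower, 2 higher and a median of -0.91, with the cystine transporter gene SLC7A11 at -3.21 and NUPR1 in the other direction at 2.82. The unfolded protein list had 12 of 19 lower and a median of -0.50, with the chaperone gene HSPA5 at -0.86. The NRF2 list had 13 of 21 lower and a median of -0.59, the cholesterol list 11 of 24 lower and a median of -0.38, and the mitochondrially encoded list 10 of 13 lower and a median of -0.73. The antigen presentation list had 8 of its 9 tested members lower and a median of -1.41, with B2M at -1.68, but most HLA genes had almost no counts in this table. The epithelial list had 13 of 23 lower and a median of -0.33, with a camera adjusted p of 0.0388 that was 0.131 under a stricter low-count filter, 0.0636 with the replicate block, 0.0609 without labelled cm-PreNeu replicate 3 and 0.0533 without genes counted low in experiment A.

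Markers of other cell types moved with the groups. Of 11 tested neutrophil markers, 8 were lower and 2 higher in the libraries labelled cm-PreNeu, with a median of -2.12 (camera adjusted p = 0.0041, adjusted p = 0.220 with an estimated correlation). S100A9 stood at 204 ± 49.5 and 1.93 ± 0.901 CPM and LCN2 at 39.0 ± 2.85 and 0.782 ± 0.272 CPM, and both genes are also made by epithelial cells. ELANE, PRTN3, AZU1 and CTSG, which encode granule proteins of neutrophil precursors, had 0 counts in every library. Of the other blood cell markers, CD79A, CD14 and CD68 were called lower, and the list had too few tested members for a set test.

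Among the 16 genes with the largest changes, most had under 0.1 CPM in 1 group. That is near or below the level of 3 counts, so the size and order of those changes are uncertain. MMP1, a collagenase, stood at 253 ± 19.7 CPM in the libraries labelled vehicle and 0.276 ± 0.331 CPM in those labelled cm-PreNeu. CEMIP, which takes part in hyaluronan breakdown, stood at 2355 ± 757 and 8.54 ± 1.61 CPM, and INHBA, a subunit of activin A, at 655 ± 65.9 and 2.15 ± 0.677 CPM. MMP10, HSD3B1, PSG3 and PSG6 completed the 8 largest lower changes after IL6; the PSG genes are near-identical copies of each other and are uncertain. In the other direction, IGFBP5, an insulin-like growth factor binding protein, had a log2 fold change of 8.91 ± 0.64 from 0.956 ± 1.21 CPM, KCNJ8 at 0.0505 ± 0.0137 and 27.5 ± 3.11 CPM, and PCDH10 at 0.109 ± 0.0469 and 15.5 ± 3.17 CPM. REG4, PZP, AGR3, NELL2 and TRGC1, the last with a near-identical copy, completed the list of largest higher changes.

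Lists of hormone and p53 targets moved in both directions. Of 34 tested oestrogen receptor targets, 15 were higher, 14 were lower and 5 were not called, with a median of -0.19, and the list was not called. RET had a log2 fold change of 2.22, and AREG, an epidermal growth factor receptor ligand, stood at 2031 ± 224 and 26.4 ± 8.95 CPM. Of 25 tested p53 targets, 8 were higher and 8 lower; BTG2 had a log2 fold change of 2.81 and GDF15 one of -3.80.

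The comparison in experiment B asks how cells under cm-PreNeu differ from cells under cm-LOX1. No single gene passed the edgeR test with 2 libraries per group without the replicate block, and 20 passed with it. The blocked fit had 1 residual degree of freedom, so its calls rest on little information about spread. Among the fixed lists the integrated stress list, which holds genes of amino acid supply, had the largest median in size among those called. Of 22 tested members of the integrated stress list, 21 had a negative log2 fold change, with a median of -0.69. Its camera adjusted p was 1.07e-13 with the preset correlation, and adjusted p = 0.818 with an estimated correlation; fry gave adjusted p = 0.929. PHGDH, which starts serine synthesis, stood at 67.2 ± 12.5 CPM under cm-LOX1 and 30.2 ± 0.346 CPM under cm-PreNeu (log2 fold change -1.15 ± 0.18, edgeR adjusted p = 0.638, and adjusted p = 0.00925 with the replicate block). CBS, of the transsulfuration route, stood at 76.2 ± 0.665 and 38.7 ± 5.04 CPM (SD, n = 2 each; log2 fold change -0.98 ± 0.16, edgeR adjusted p = 0.638, and adjusted p = 0.0206 with the block). The DNA replication list lay in the other direction, with 39 of 40 members positive and a median of 0.31 (camera adjusted p = 2.29e-15, adjusted p = 0.818 with an estimated correlation, and 0.929 with fry).

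Of 14714 tested genes, edgeR called 0, with 224 at an unadjusted p under 0.05 and a smallest adjusted p of 0.273; DESeq2 called 11 (4 higher, 7 lower) and limma-voom called 0. The groups did not overlap for 23.0% of tested genes, where chance gives 33.3%. With the replicate block, 20 genes were called, 8 higher and 12 lower. The blocked calls included ASNS (log2 fold change -1.47), SLC7A5 (-1.41), SLC7A11 (-1.17), PHGDH (-1.14), CBS (-0.98) and SLC3A2 (-0.89), which encode asparagine synthetase, amino acid transporters and enzymes of serine and cysteine synthesis. OXTR (0.93), the oxytocin receptor gene, and SULF1 (-0.80) were also called. Without the block the unadjusted edgeR p was 0.265 for OXTR, 0.078 for SLC3A2 and 0.0112 for SULF1. SMIM11 (-1.60) was called too and is uncertain. ENSG00000273590, a copy of it, went from 0 to 5.61 ± 1.84 CPM while SMIM11 went from 9.90 ± 1.14 to 3.25 ± 0.173. Their sum stood at 9.90 ± 1.14 and 8.86 ± 1.67 CPM. The sum and the genes outside the 5 of smallest p were chosen after their values were seen. The other 11 blocked calls were read-through transcripts, unnamed identifiers or near-identical copies with 1 group near 0 counts, such as EIF3CL at 16.3 ± 9.86 and 0 CPM, and are uncertain. The 5 genes of smallest p that met the conditions on symbol, count and overlap were EIF3CL, PHGDH, CBS, SMIM11 (log2 fold change -1.61) and ASS1 (-0.90). The 5 of smallest p without those conditions were ENSG00000273590, EIF3CL, ENSG00000289733, ENSG00000285901 and SEC22B3P.

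None of the fixed repair genes was called in experiment B, where 10.2% of simulated changes of 1.5-fold were called. BRCA1 had a log2 fold change of 0.09 ± 0.14, BRCA2 one of 0.16 ± 0.21, PALB2 one of 0.10 ± 0.16, and PARP1 one of 0.08 ± 0.17. RAD51 stood at 15.0 ± 3.11 CPM under cm-LOX1 and 21.2 ± 1.49 CPM under cm-PreNeu (log2 fold change 0.51 ± 0.22), and 0.31 to 0.73 with 1 library left out. ESR1 had a log2 fold change of -0.42 ± 0.17, TP53 one of -0.24 ± 0.15, MKI67 one of 0.09 ± 0.14 and CDKN1A one of -0.02 ± 0.16. The homologous recombination list had 29 of 42 members positive and a median of 0.10 (camera adjusted p = 0.0164, adjusted p = 0.818 with an estimated correlation). Its call was lost without cm-LOX1 replicate 1, cm-PreNeu replicate 1 or cm-PreNeu replicate 2, in fits that left 1 library in a group. Within same-numbered pairs its median was 0.24 and 0.03.

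With an estimated correlation no list of experiment B was called: antigen presentation, Fanconi anaemia and TGF-beta each had adjusted p = 0.818, unfolded protein 0.829, oxidative phosphorylation 0.839 and mitochondrially encoded genes 0.860, and fry called 0 lists. In the integrated stress list, 3 members were called when adjusted over the list alone. Its median was -0.34 without cm-LOX1 replicate 1, -0.50 without cm-PreNeu replicate 2 and -1.09 without cm-PreNeu replicate 1, and the list was called in each case. All 20 members of the unfolded protein list were negative, with a median of -0.29 (camera adjusted p = 0.000331), but without cm-LOX1 replicate 1 the median was 0.01 (adjusted p = 0.794), and without cm-PreNeu replicate 2 the call was also lost (adjusted p = 0.0817). The antigen presentation list had 15 of 17 members negative and a median of -0.18, the Fanconi anaemia list 16 of 20 positive and a median of 0.14, and the TGF-beta list 13 of 20 positive and a median of 0.15. Without cm-LOX1 replicate 1 none of these 3 was called (adjusted p = 0.319, 0.298 and 0.558), nor without cm-PreNeu replicate 2 (adjusted p = 0.506, 0.235 and 0.126), and antigen presentation was also not called without cm-LOX1 replicate 2 (adjusted p = 0.149). Under the stricter low-count filter antigen presentation (median -0.07, adjusted p = 0.0661) and TGF-beta (0.06, adjusted p = 0.164) were not called. The mitochondrially encoded list (median 0.12) and the oxidative phosphorylation list (0.08) were called without the block and not with it (adjusted p = 0.0533 and 0.0611). The former was not called without cm-LOX1 replicate 1, cm-PreNeu replicate 1 or cm-PreNeu replicate 2 (adjusted p = 0.794, 0.305 and 0.126), and the latter not with any 1 library left out (adjusted p from 0.0551 to 0.525). The mitosis list, which differed most among the higher lists of experiment A, had a median of -0.04 and was not called.

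**Figure D2:**
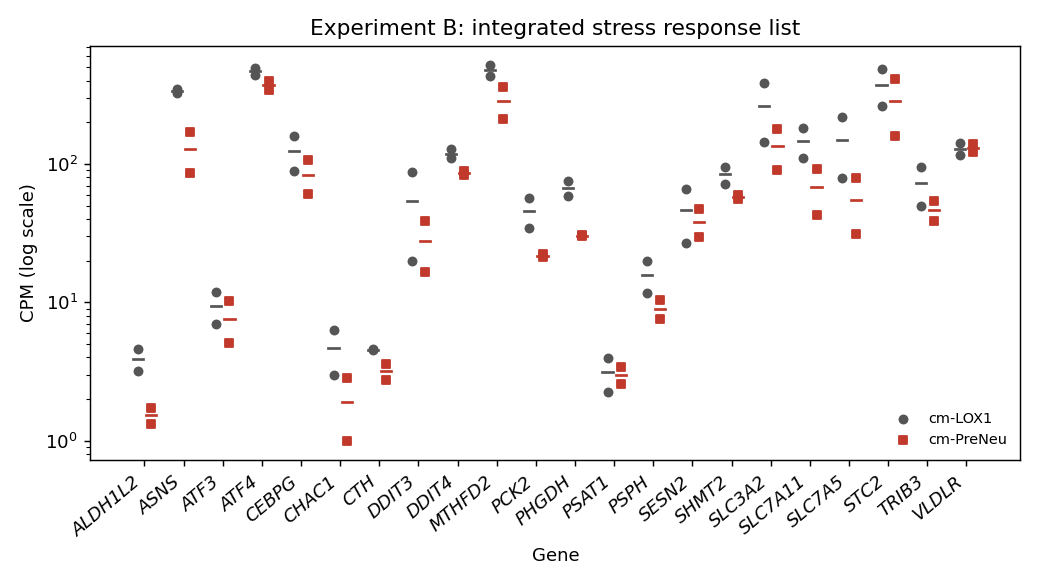
CPM on a log scale (vertical axis) of the 22 tested integrated stress genes (horizontal axis) in the 2 cm-LOX1 libraries (grey circles) and the 2 cm-PreNeu libraries (red squares) of experiment B, with a bar at each group mean. Most means are lower under cm-PreNeu, with a list median log2 fold change of -0.69, while the libraries of a group are often far apart.

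**Figure D3:**
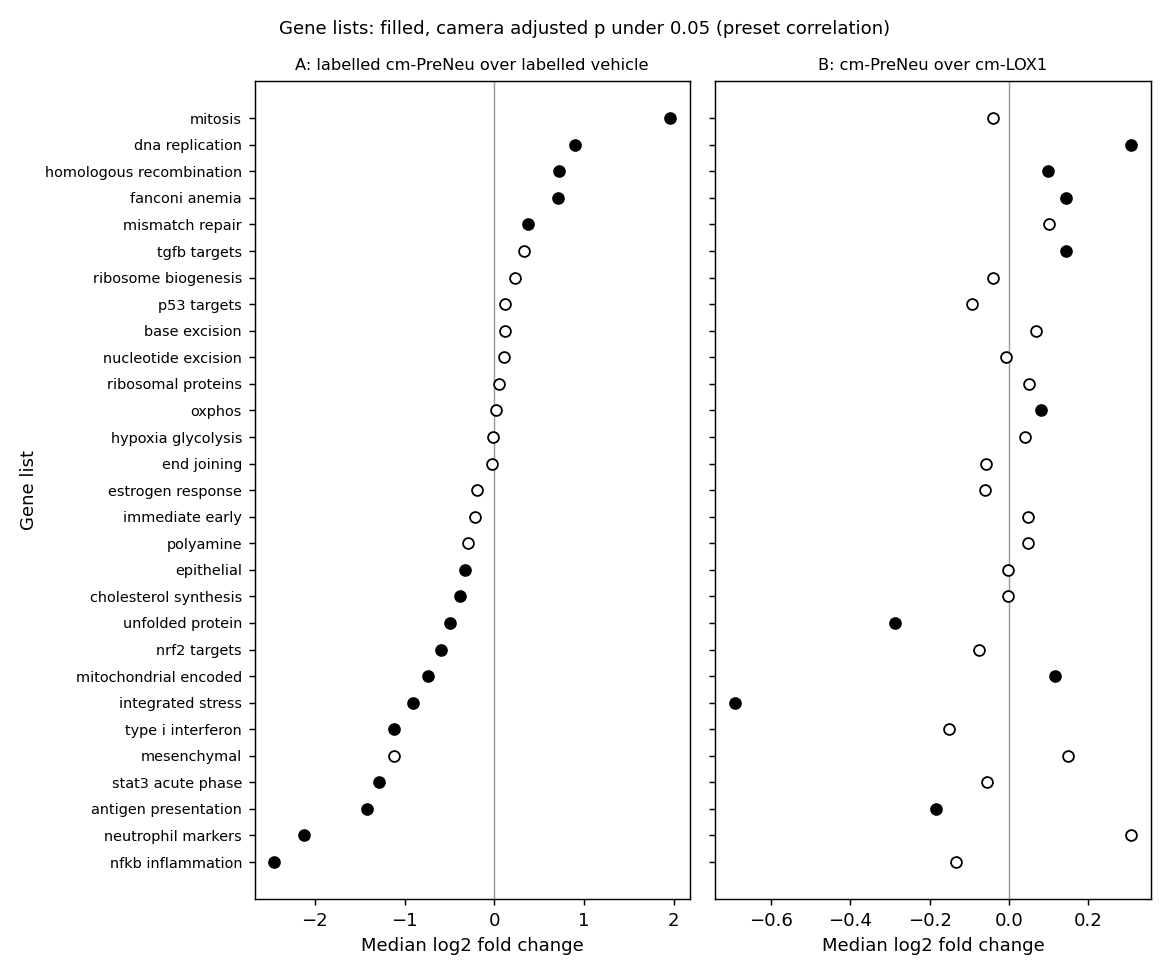
Median log2 fold change (horizontal axes, on different scales) of each tested gene list (vertical axis) in experiment A, labelled cm-PreNeu over labelled vehicle, and in experiment B, cm-PreNeu over cm-LOX1; filled points have a camera adjusted p under 0.05 with the preset correlation. Mitosis lies highest in experiment A at 1.96 and at -0.04 in experiment B, and integrated stress lies below 0 in both.

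The 2 experiments were set side by side to ask whether their contrasts share a direction. Across 13050 genes tested in both, the fold changes correlated at Pearson's r = -0.044 and Spearman's rho = 0.00152, and 51.3% of genes had the same sign, or 48.7% if the headers of experiment A are right. This is a description across genes, which are not independent replicates. Of 20 combinations of splits that part both same-numbered pairs of experiment B, 7 had a correlation at least as large in size, the real one included, and the largest of the others was 0.112. The split that sets 1 pair of experiment B against the other gave sizes of 0.233 to 0.420 in its 10 combinations; setting it apart was chosen after the values of all 30 were seen. The correlation was -0.236 without cm-LOX1 replicate 1, -0.215 without cm-PreNeu replicate 2, 0.160 without cm-LOX1 replicate 2 and 0.172 without cm-PreNeu replicate 1 of experiment B. Each of these fits left 1 library in a group of experiment B and mixed the pair difference with the treatment. Of 7 genes called in experiment A and in the blocked fit of experiment B, 6 had the same direction by the titles of experiment A and 1 if its headers are right. The integrated stress list had a negative median in both experiments (-0.91 and -0.69) and the replication list a positive one (0.89 and 0.31), with the direction in experiment A resting on its titles. Other lists did not go together. The mitochondrially encoded list, called in both with the preset correlation, had medians of -0.73 and 0.12, and the mitosis list 1.96 and -0.04.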

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

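The removal of genes counted low in experiment A was chosen after seeing the data; it left 15 called lists. In experiment A the number of called genes stayed between 6270 and 9889 under every alternative fixed in advance and between 7275 and 8708 with 1 library left out; the replicate block gave 9480, and same-numbered libraries correlated in their deviations at -0.00536, 0.278 and 0.298. The number of called lists was 0 with an estimated correlation, where the homologous recombination list (median 0.72) lost its call, and 14 to 17 with 1 library left out. With fry it was 21 (6 higher, 15 lower), homologous recombination among them (fry adjusted p = 0.00427). That test does not set a list against the other genes, of which 53.8% of all tested were called. The block ended the call of the epithelial list (adjusted p = 0.0636) and of no other list in experiment A. In experiment B, 103 genes were called without the low-count filter, 20 with the block, 11 with DESeq2, 1 with all 10 libraries in 1 fit, and 0 to 8 with 1 library left out; called lists numbered 0 with an estimated correlation, 0 with fry and 3 to 10 with 1 library left out. The homologous recombination list of experiment B (0.10) lost its call with an estimated correlation and with fry, and its median ranged from 0.0496 to 0.169 with 1 library left out; the cause was not tested. The correlation of fold changes between experiments ranged from -0.236 to 0.172 with 1 library left out. Lists that changed sign in experiment B with 1 library left out were mismatch repair (-0.0101 to 0.276), mitosis (-0.0629 to 0.00237), NF-kB (-0.518 to 0.545), type I interferon (-0.275 to 0.134), STAT3 (-0.381 to 0.223), unfolded protein (-0.494 to 0.00795), cholesterol (-0.128 to 0.114), epithelial (-0.151 to 0.144) and neutrophil markers (-0.117 to 0.46). Of these only the unfolded protein list was called with all 4 libraries. NF-kB, type I interferon and STAT3 gained calls in some of these fits. Each fit left 1 library in a group and mixed the pair difference with the treatment, so those calls are not read as treatment effects. Within same-numbered pairs the medians were -0.16 and 0.02 for NF-kB, 0.11 and -0.38 for type I interferon, and -0.08 and -0.23 for STAT3. Cholesterol was 0.0073 and epithelial 0.0115 under the stricter filter, and 0.00238 and 0.00551 with the block. Among genes, BRCA2 (-0.064 to 0.417), PARP1 (-0.108 to 0.303) and CDKN1A (-0.152 to 0.121) changed sign. In experiment A the oxidative phosphorylation list was -0.00343 with RLE factors and -0.0152 to 0.11 with 1 library left out. The 11 lists called in neither experiment are not followed singly; 8 of their 132 values under alternatives in experiment A and 19 of 98 in experiment B changed sign, and 14 and 11 passed the threshold, in experiment A among base excision, hypoxia, polyamine, mesenchymal, ribosome biogenesis, immediate early and ribosomal protein lists. At the depth, number of libraries and spread of experiment B, a 2-fold change was called for 34% of simulated genes, against 68% in experiment A. Few genes were changed in the simulation, whereas 53.8% of genes were called in experiment A, so its shares do not give the share of real changes found there.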

Other observations

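The tests of exchanged titles and of carried-over neutrophil RNA were chosen after the result was seen; the other tests were chosen before. DUSP6, a feedback phosphatase of the ERK pathway, stood at 65.9 ± 6.47 CPM in the libraries labelled vehicle and 3.09 ± 1.08 CPM in those labelled cm-PreNeu, and FOSL1, a member of the AP-1 family, at 18.5 ± 1.77 and 0.794 ± 0.151 CPM. The immediate early list was not called (7 lower and 3 higher of 21). ITGA5 (log2 fold change -3.49), CD44 (-2.48) and FN1 (-2.60) were lower and S100A4 (2.05) was higher, and the mesenchymal list was not called. In the hypoxia list, also not called, VEGFA had a log2 fold change of -2.28 and PFKFB3 one of 1.49. The polyamine list (median -0.29), the ribosome biogenesis list (0.23) and the ribosomal protein list (0.05) were not called, and neither was the TGF-beta list (0.33) or the oxidative phosphorylation list (0.01).

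The first pattern is the direction of experiment A, in which the column headers contradict the titles; which libraries received conditioned medium stays open. An axis was drawn from labelled vehicle (0) to labelled cm-PreNeu (1) over 7291 genes called in experiment A. The 4 libraries of experiment B, all under conditioned medium by their labels, lay on it between 0.440 and 0.624. They lay between the groups on average, so this position cannot tell an exchange of titles from a correct labelling. That average covers values on both sides: by list the mean position ran from -1.21 to 2.23. Of the 16 genes with the largest changes in experiment A, 12 or 13 were nearer the labelled vehicle level in experiment B, depending on the pseudocount (0.01 to 2 CPM). With all 10 libraries scaled together, INHBA stood at 641 CPM in labelled vehicle and 2.11 CPM in labelled cm-PreNeu. In experiment B it stood at 215 ± 125 CPM under cm-LOX1 and 209 ± 134 CPM under cm-PreNeu. REG4 and IL6 were nearer the labelled cm-PreNeu level at each pseudocount. IL6 lay between 42.0 and 0.0899 CPM, at 1.90 ± 2.36 CPM under cm-LOX1 and 1.70 ± 1.52 CPM under cm-PreNeu. The count and these genes were chosen after their values were seen. The axis explained 0.0296% of the variance between experiment B and the midpoint of experiment A, which follows from positions near the middle and is no separate evidence for a difference between the experiments alone. RNA of neutrophils carried over in the medium is argued against as the source of the S100A9 and LCN2 differences. In the group with more marker RNA, S100A9 stood at 9467 and LCN2 at 1811 counts per library. There the median of 18 neutrophil genes, of granules, surface and others, was 0 counts per library. That of all 30 neutrophil markers fixed in advance was 0.667. These medians do not settle the source of each other marker. The markers called lower besides S100A9 and LCN2 were CD177 (34.7 against 9.33 counts per library), S100A12 (30.3 against 0), SRGN (46.3 against 0), S100A8 (26.7 against 0.333), ITGAM (169 against 72.3) and CSF3R (27.3 against 11.3), and their source was not tested.

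The second pattern is the higher homologous recombination list in the libraries labelled cm-PreNeu, called with the preset correlation and with fry (fry adjusted p = 0.00427) and not with an estimated correlation (camera adjusted p = 0.498). The TMM factors lowered the fold changes of all genes alike, by 0.24 log2, so they did not raise the list. Its median was 0.95 with library sizes alone, where that of all genes was 0.26. The factors fixed this shift in advance, so it does not test scaling as the source. Other errors of scaling were not tested. A larger share of cycling cells stays open: the 20 members known to peak in S phase or G2 had a median of 1.15 and the other 21 one of 0.26 (bootstrap interval over genes 0.11 to 0.59), which is neither near 0 nor clearly above it by the margin set in advance, so a cell cycle effect and a separate repair effect cannot be told apart. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05; the real split gave a median of 0.72 and the highest of the others 0.35 (1 split as large), 8922 called genes against 0 (1 split as large), and 16 called lists against 16 (2 splits as large). The count of called lists with the preset correlation therefore did not set the real split apart from mixed ones. Every other split mixes libraries of both groups, so it keeps part of the group difference and adds the rest to the spread within groups. The 0 called genes and the 16 called lists of mixed splits are therefore no measure of what chance alone gives.

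The third pattern is the negative median of the integrated stress and unfolded protein lists in experiment B, cm-PreNeu over cm-LOX1; both were called with the preset correlation, but not with an estimated correlation (adjusted p = 0.818 and 0.829) or fry (adjusted p = 0.929 for each), and edgeR called no member over all genes without the block. The integrated stress list had a median of -0.75 in 1 pair of same-numbered libraries and -0.59 in the other, which argues against a single pair as its source, whereas the unfolded protein list had -0.44 in 1 pair and -0.0392 in the other, consistent with 1 pair carrying it. As a hypothesis, ATF4 activity may be lower under cm-PreNeu than under cm-LOX1: 13 tRNA synthetase and export genes known as ATF4 targets, none in the list, had a median of -0.60 and 7 other synthetases one of -0.00, a difference of -0.59 (exact two-sided permutation over genes, p = 0.00108, though genes are not independent). Without a vehicle library in experiment B, whether cm-PreNeu lowers or cm-LOX1 raises these genes stays open, and so does a difference in nutrients between the media.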
